A study of Mus musculus with 14 samples.

How the data were processed

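The libraries were made from mouse oocytes in lysis buffer with SMART-Seq2, a method that copies and amplifies full-length cDNA from very small amounts of RNA. The labels do not state how many oocytes or animals went into a library or how the samples were batched. Per the labels, CKO mice carried Zp3-Cre, which is expressed from the promoter of a zona pellucida gene in growing oocytes. Groups were taken from the labels: 4 GV WT, 4 GV CKO, 3 ovulated WT and 3 ovulated CKO libraries.

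The authors deposited, for each stage, a table of read counts and a table of FPKM values, with 1 column per library. The deposited count values are expected counts, estimated per gene and not scaled to library size, since between 14.45% and 16.32% of the values of a library were fractional. The deposited FPKM values are counts scaled by the authors to gene length and library size. To match columns, log counts and log FPKM of well-covered genes were used, with each gene's mean over the libraries of its stage subtracted. These deviations correlated across genes at an r of at least 0.986 with the library's own FPKM column. With another library's column r was no more than 0.596, which measures deviations and not the likeness of expression levels. The authors state mouse genome build mm10 and no aligner, counting tool or annotation. The 18 pairs of replicates within groups were checked for copied columns and differed far beyond counting error (chi-square per degree of freedom from 40.5 to 325). Chromosome positions came from the RefSeq annotation of the same build, and 18509 of 18562 gene IDs were found in it.

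Total counts per library were between 25086506 and 28471453. Counting intervals cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

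None of the 13 protein-coding genes of the mitochondrial DNA was listed in either count table. The share of counts from the mitochondrial DNA and the list of mitochondrial DNA-encoded mRNAs, which had been planned, were therefore not analysed here.

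The comparisons, lists, rule for named genes and alternatives were fixed before the data were examined, apart from the average of the effects of both stages, which was added after the data had been seen. Expected counts were rounded to whole counts. Genotypes were compared within each stage on that stage's libraries alone with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood F-test), in R 4.3.3. The stage difference of the CKO effect, the WT comparison of ovulated against GV oocytes and the average of both stages came from a fit of the 14 libraries with 4 groups, on genes listed in both tables. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. Fold changes are CKO over WT, or ovulated over GV. CPM values are counts divided by the TMM-scaled library size in units of 1e+06.

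Of 31 gene lists fixed in advance, 30 had at least 5 tested genes in each comparison. They covered mitochondrial proteostasis, the integrated stress response, the endoplasmic reticulum unfolded protein response, heat shock chaperones, the respiratory chain, mitochondrial and cytosolic ribosomes, mitochondrial DNA maintenance, mitochondrial import, energy metabolism, heme and iron-sulfur clusters, antioxidant defence, autophagy, apoptosis, DNA repair, oocyte factors, maternal-effect genes, meiosis, maternal mRNA storage and decay, fertilisation, lipid synthesis, the proteasome, zygotic genome activation, interferon response, histones and markers of other ovarian cells. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera ranks a list against the other genes, whereas fry asks whether the genes of a list move 1 way on balance.

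The rule named Clpx and Clpp, then up to 8 genes in each direction with the largest fold change among genes that passed, had a mean of at least 10 CPM and no overlap of the groups, leaving out predicted genes. Where fewer than 4 genes passed, it named the 10 genes with the smallest p-values and at least 10 CPM, said not to pass. From the lists it named up to 4 members that passed, or the 2 with the smallest p-values in a list called as a set. The stage comparisons named up to 5 genes in each direction and 2 members per list. Some genes that the rule would name are not reported.

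On simulated counts with 100 genes changed by each fold, the edgeR test recovered 53% of changes of 2-fold and 98% of changes of 4-fold in the GV design. It recovered 5% and 66% in the ovulated design, 2% and 48% for the stage difference, and 20% and 94% for the WT stages. The changed genes had a mean of at least 10 CPM and genes varied independently of each other. These shares hold for that setting and may differ in the real libraries. Genes with at least 1 count were counted per library and compared by exact permutation tests.

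Alternatives were DESeq2 size factors, scaling to total counts, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no filter, a minimum of 10 CPM, limma-trend on log2 FPKM with 1 or 0.1 added, a fold threshold of 1 on the log2 scale, the 14 libraries in 1 fit, a replicate block, and leaving out each library. Counts of called genes and lists were compared with other splits of the same libraries, all splits within a stage or between the WT stages and 100 drawn splits for fits of the 14 libraries. Protein-coding transcripts of the listed genes, found by symbol, were searched against mitochondrial transcripts with blastn 2.17.0. Noncoding transcripts and pseudogenes were not searched.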

Results

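RNA was measured in 14 libraries of mouse oocytes at 2 stages, from mice with floxed Clpx and the Zp3-Cre transgene, which deletes it in oocytes (labelled CKO), and from mice with the floxed gene and no Cre (labelled WT). CLPX is the unfoldase subunit of a protease in the mitochondrial matrix. Germinal vesicle (GV) oocytes are arrested in meiotic prophase with an intact nucleus, and ovulated oocytes have resumed meiosis and left the follicle. The GV stage had 4 WT and 4 CKO libraries and the ovulated stage had 3 WT and 3 CKO libraries. The total estimated read count per library was between 25086506 and 28471453. The GV table listed 18076 genes, the one for ovulated oocytes listed 16903, and 16417 genes were in both. Single genes took large shares of the GV libraries, with Clec16a holding 4.97% to 8.76% of the counts in the 8 GV libraries. Positions are on mouse build mm10, and gene identifiers are the numeric gene IDs of the tables.

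The first comparison asked what loss of Clpx changed in GV oocytes. Clpx fell 40.2-fold, from 38.6 ± 8.64 CPM (counts scaled to library size; SD, n = 4) in WT to 0.961 ± 0.333 CPM (SD, n = 4) in CKO. Mt1, which encodes a metal-binding metallothionein, rose 60.5-fold, from 1.65 ± 0.727 CPM (SD, n = 4) to 99.5 ± 14.2 CPM (SD, n = 4). The predicted gene Gm20594 rose 8.46-fold, from 15.5 ± 2.59 CPM (SD, n = 4) to 131 ± 41 CPM (SD, n = 4). These 3 genes, 2 higher and 1 lower in CKO, passed an edgeR adjusted p of 0.05 among 12265 genes tested. Genes for the cytosolic ribosome, for the respiratory chain and for histones ranked higher in CKO as sets, by small amounts, without a single member past the threshold, and with no call at an estimated correlation (adjusted p from 0.46 to 0.771).

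Clpx (gene ID 270166, chromosome 9, 65294251 to 65330658) had a log2 fold change of −5.33 (SE 0.305, edgeR adjusted p = 6.48e-06). Mt1 (gene ID 17748, chromosome 8, 94178883 to 94180327) had a log2 fold change of 5.92 (SE 0.354, edgeR adjusted p = 6.48e-06). Gm20594 (gene ID 100463512, chromosome 6, 79818031 to 79818364) had a log2 fold change of 3.08 (SE 0.244, edgeR adjusted p = 0.000108). Gm20594 lay outside the rule for named genes and was chosen after its values were seen. For each of these genes the 4 CKO libraries lay entirely to 1 side of the 4 WT libraries. The Gm20594 transcript matched the mitochondrial large ribosomal RNA with 88.506% identity, in an alignment of 435 positions that covered bases 1 to 432 of its 449 bases. Clpp, the peptidase that CLPX feeds, stood at 9.62 ± 2.35 CPM (SD, n = 4) in WT and 10.1 ± 2.57 CPM (SD, n = 4) in CKO, a log2 fold change of 0.07 (edgeR adjusted p = 0.965) whose sign turned under scaling to total counts (−0.13).

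**Figure D1:**
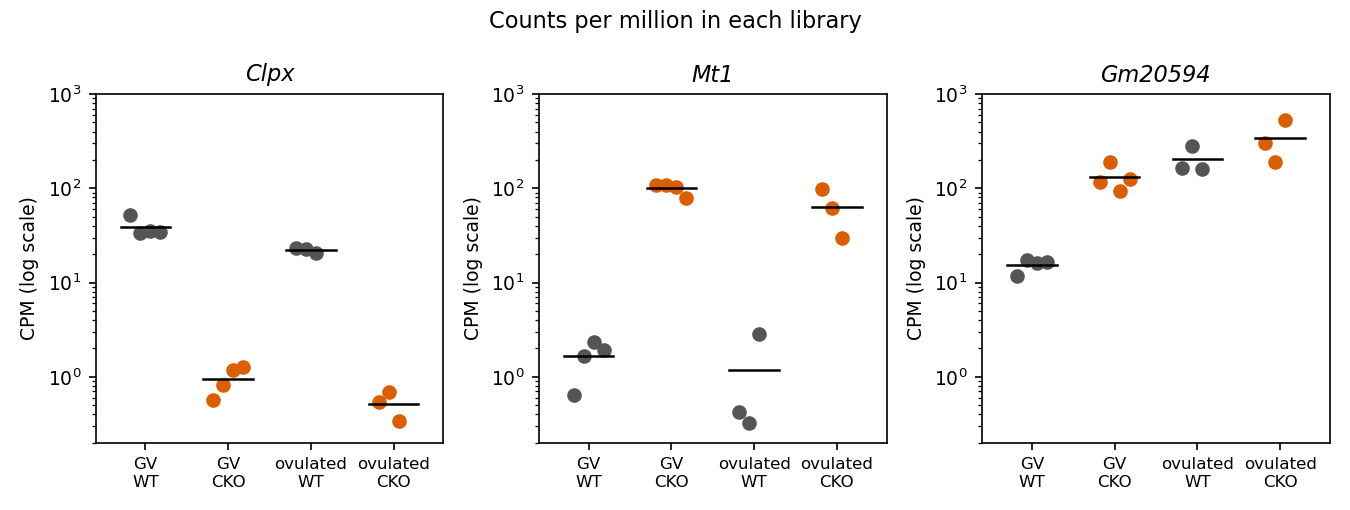
CPM (log axis) of Clpx, Mt1 and Gm20594 in each of the 14 libraries, with grey points for WT, orange points for CKO and a black line at each group's mean (SD in the text). Clpx lay between 20.7 and 51.5 CPM in the WT libraries and between 0.342 and 1.28 CPM in the CKO libraries, and Mt1 was at most 2.83 CPM in the WT libraries and at least 29.6 CPM in the CKO libraries.

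The 10 genes with the next smallest p-values at a mean of at least 10 CPM did not pass the edgeR test. Among those higher in the CKO means were the predicted gene Gm29797 (log2 fold change 1.18, adjusted p = 0.0836), Gli3, a transcription factor of Hedgehog signalling (2.03, adjusted p = 0.243), and the predicted gene Gm4907 (1.79, adjusted p = 0.416). Fbxo16 had a log2 fold change of 0.99 and Prex2 of 0.76. Among those lower in the CKO means were Myo1e, an unconventional myosin (−1.37, adjusted p = 0.15), Slc44a4 (−0.94), the surface glycoprotein gene Cd200 (−1.10), Gtf2ird1 (−0.67) and the chemokine receptor gene Cxcr3 (−0.98). Gm4907 was the 1 gene of these 10 whose CKO and WT libraries overlapped. At an unadjusted edgeR p under 0.05 there were 704 genes, where the test's nominal rate gives 613.2. Other splits of the GV libraries gave between 58 and 2376 genes, so this excess cannot be read as an effect of genotype.

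Of the 30 gene lists tested in GV oocytes, 6 ranked higher in CKO by camera with a preset correlation of 0.01, and none of them with an estimated correlation. The count was 3 without WT replicate 3 and 10 without WT replicate 4. All 78 cytosolic ribosomal protein genes had higher CKO than WT means (median log2 fold change 0.35, adjusted p = 1.84e-17), for example Rpl23 (0.61) and Rpl37 (0.51). Of the 40 genes for respiratory complexes II to V, 33 had higher CKO means (median 0.24, adjusted p = 2.07e-05), for example the cytochrome c gene Cycs (0.46) and the cytochrome oxidase subunit gene Cox7b (0.45). Of the 36 complex I genes, 29 had higher CKO means (median 0.13, adjusted p = 0.0069), for example Ndufab1 (0.42) and Ndufa2 (0.36). Of 77 mitochondrial ribosomal protein genes, 51 had higher CKO means (median 0.10, adjusted p = 0.0256), for example Mrps33 (0.54) and Mrpl34 (0.37). All 11 replication-dependent histone genes tested, of 28 in the list, had higher CKO means (median 0.54, adjusted p = 2.07e-05). Examples were H2bc4 (0.72) and H2ac18 (0.76), and 3 of the 11 passed when adjusted over the list alone. The mean level of the 11 was low, at 0.86 log2 CPM in GV WT and 1.42 in GV CKO libraries. The highest WT library and the lowest CKO library met at 1.15 log2 CPM. Of 30 genes for oocyte transcription factors, the zona pellucida and secreted factors, 25 had higher CKO means (median 0.21, adjusted p = 0.0331), for example Dazl (0.80) and Omt2a (0.54).

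With an estimated correlation the histone list had adjusted p = 0.46 and the other 5 lists had adjusted p = 0.771. Scaling to total counts shifted the median of all genes by −0.164, and under it the medians were 0.21 for cytosolic ribosomal proteins, 0.12 for complexes II to V, 0.45 for histones, 0.01 for complex I, −0.03 for mitochondrial ribosomal proteins and −0.00347 for the oocyte factor list.

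The other 24 lists were not called in GV oocytes. The list of mitochondrial proteases, chaperones and the mitochondrial unfolded protein response had a median log2 fold change of 0.03 over 27 genes (camera adjusted p = 0.621). The integrated stress response and ATF4 targets had a median of −0.06 over 33 genes (adjusted p = 0.111), the endoplasmic reticulum unfolded protein response −0.04 (adjusted p = 0.678) and the cytosolic heat shock chaperones 0.11 (adjusted p = 0.294). Mitochondrial import and dynamics had a median of 0.15 (adjusted p = 0.0876), mitochondrial DNA maintenance, transcription and translation factors −0.06 (adjusted p = 0.563) and the tricarboxylic acid cycle −0.01 (adjusted p = 0.678). Fatty acid oxidation had −0.12 (adjusted p = 0.192), glycolysis and the pentose phosphate pathway −0.06 (adjusted p = 0.242), heme and iron-sulfur cluster synthesis −0.06 (adjusted p = 0.607), and cholesterol and lipid synthesis −0.15 (adjusted p = 0.114). Antioxidant defence had a median of 0.04 but a mean of −0.05 (adjusted p = 0.969), the 1 list whose median, mean and test differed in sign. Autophagy and mitophagy had −0.02 (adjusted p = 0.678), the p53 response and apoptosis −0.05 (adjusted p = 0.737), and DNA damage checkpoint and repair −0.01 (adjusted p = 0.678). Maternal-effect genes had 0.17 (adjusted p = 0.192), meiotic cell cycle, spindle and cohesin genes 0.06 (adjusted p = 0.643), maternal mRNA storage, polyadenylation and decay 0.09 (adjusted p = 0.369), and fertilisation, egg calcium signalling and cortical granules 0.09 (adjusted p = 0.369). Proteasome subunits had 0.06 (adjusted p = 0.0876) and zygotic genome activation genes 0.37 over 13 genes (adjusted p = 0.0876). The interferon and innate immune response list had −0.05 (adjusted p = 0.612), with 1 of its 14 genes lower when adjusted over the list alone. Markers of granulosa and cumulus cells had −0.18 over 11 genes (adjusted p = 0.196), and markers of theca, stromal, endothelial and blood cells −0.15 over 6 genes (adjusted p = 0.294).

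GV WT libraries held 15740 ± 210 genes with a count (SD, n = 4) and GV CKO libraries 15337 ± 334 (SD, n = 4). The difference of −402.5 genes did not pass a two-sided exact permutation test (p = 0.114, where 0.0286 is the smallest p that 4 against 4 libraries allow). With libraries thinned to the smallest total the difference was −370 genes (exact p = 0.171), and without CKO replicate 3 it was −557 genes (exact p = 0.0286). Replicate 3 held the most genes in both genotypes (16031 in WT, 15802 in CKO), so leaving out its CKO library alone widens the difference. Each CKO library held fewer genes than the WT library of its number. The labels give no pairing and no paired test was run, so variation shared by number, if any, counts as noise in these tests. For the counts of changed genes, DESeq2 called 39 genes in the same libraries (14 higher, 25 lower) and limma-voom 6, and leaving out CKO replicate 1 or CKO replicate 4 gave 6 in edgeR. On simulated counts of this design, with 200 genes changed, DESeq2 called 32 unchanged genes, edgeR 7 and limma-voom 5. Simulated genes varied independently of each other, so these are not the false calls to expect in the real libraries.

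The second comparison asked what loss of Clpx changed in ovulated oocytes. Clpx fell 41.8-fold, from 22.2 ± 1.32 CPM (SD, n = 3) in WT to 0.522 ± 0.174 CPM (SD, n = 3) in CKO. Mt1 stood at 1.19 ± 1.42 CPM (SD, n = 3) in WT and 63 ± 34.4 CPM (SD, n = 3) in CKO, with each CKO library above each WT library. Genes for respiratory complex I ranked higher in CKO as a set, with 35 of 36 higher in the CKO means and a median log2 fold change of 1.24, a call that was lost with an estimated correlation (adjusted p = 0.881). The 3 CKO libraries were not alike in this. Replicates 1 and 2 had mean complex I levels of 5.19 and 4.42 log2 CPM, and replicate 3 had 3.04, inside the WT range of 2.44 to 3.64.

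Clpx was the 1 gene of 12044 that passed in edgeR, with a log2 fold change of −5.39 (SE 0.441, edgeR adjusted p = 0.00123). Mt1 had a log2 fold change of 5.72 (SE 0.825) and did not pass (edgeR adjusted p = 0.153). Clpp had a log2 fold change of 1.58 (SE 0.997, edgeR adjusted p = 0.737) at levels below 1 CPM in both groups.

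The other genes with the smallest p-values had adjusted p = 0.524 in edgeR and stood higher in the CKO means, apart from Teddm1b (−1.68). They included the proteasome subunit gene Psmb7 (log2 fold change 4.08), Chchd2, which encodes a mitochondrial protein (3.77), Slirp, which encodes a mitochondrial RNA-binding protein (3.71), Yipf1 (3.32), Tmem29 (3.21), the cytochrome b5 gene Cyb5a (2.91) and Rsl24d1 (1.69), a ribosome biogenesis gene. CKO and WT libraries overlapped for Psmb7 and Chchd2. Their lowest CKO values, 3.5 and 7.52 CPM, lay inside the WT ranges of 2.31 to 5.54 and 4.07 to 12.85 CPM. At an unadjusted edgeR p under 0.05 there were 935 genes, where the test's nominal rate gives 602.2. Other splits of the ovulated libraries gave between 96 and 3118 genes, so this excess cannot be read as an effect of genotype either. CKO and WT libraries did not overlap for 10.4% of the genes, where chance gives 10% for 3 against 3.

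Of the 30 lists tested in ovulated oocytes, 4 ranked higher in CKO by camera with the preset correlation, and none of them with an estimated correlation. The count was 1 without WT replicate 1 or CKO replicate 1, and 6 without WT replicate 2 or CKO replicate 2. Complex I had adjusted p = 4.02e-10, with Ndufa5 (2.78) and Ndufa2 (2.18) as examples. Complexes II to V had 31 of 40 genes higher in the CKO means (median 0.73, adjusted p = 2.79e-05), for example the cytochrome oxidase subunit genes Cox7c (3.69) and Cox7b (3.12). Cytosolic ribosomal proteins had 60 of 78 genes higher (median 0.84, adjusted p = 4.49e-05), for example Rps13 (2.94) and Rpl37 (2.12). Mitochondrial import and dynamics had 23 of 31 genes higher (median 0.50, adjusted p = 0.00457), for example the outer membrane translocase genes Tomm40 (3.45) and Tomm6 (2.39). Tomm40 was low in ovulated WT libraries, at a mean of 0.551 CPM, and its lowest CKO library was at 0.513 CPM. In each of these 4 lists the mean of CKO replicate 3 lay inside the WT range, at 4.04 log2 CPM for complexes II to V (WT 3.45 to 4.65), 3.13 for cytosolic ribosomal proteins (WT 2.46 to 4.03) and 4.10 for mitochondrial import (WT 3.64 to 4.46). With an estimated correlation each of them had adjusted p = 0.881. No member of these lists passed over all genes tested or adjusted over the list alone. Outside them, 3 proteasome genes and 1 gene of mitochondrial DNA maintenance, transcription and translation were higher when adjusted over the list alone.

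The mitochondrial unfolded protein response list had a median of 0.09 (adjusted p = 0.765) and the integrated stress response list −0.08 (adjusted p = 0.643) in ovulated oocytes. The other lists not called had medians from −0.37, for markers of theca, stromal, endothelial and blood cells, to 0.33, for zygotic genome activation genes. Median, mean and test differed in sign in 9 of the 30 lists.

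**Figure D2:**
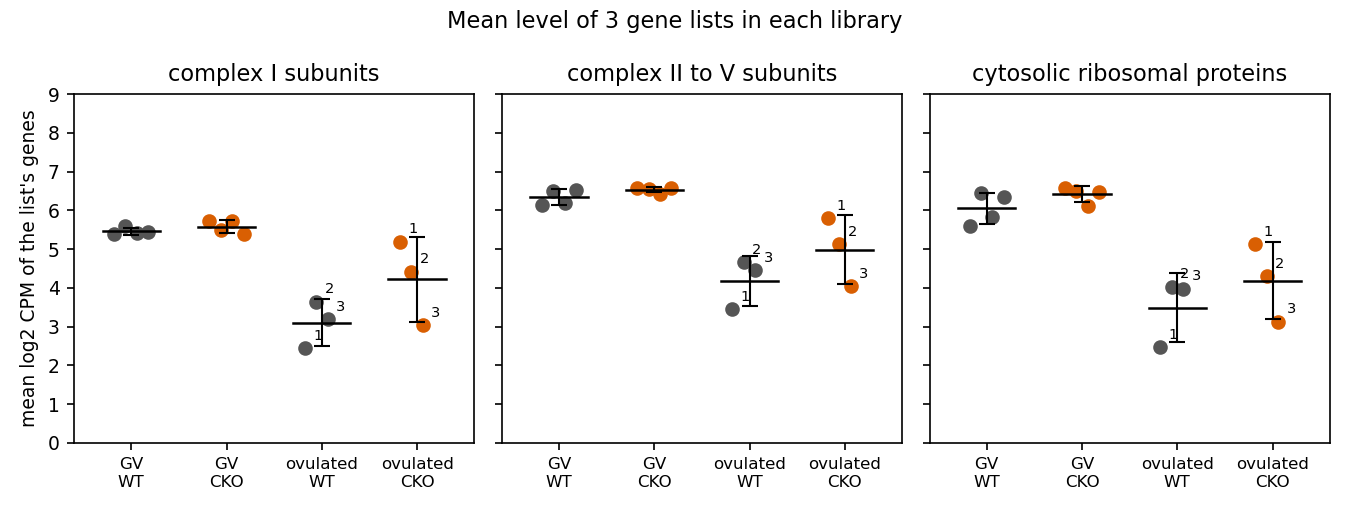
Mean log2 CPM, scaled within each stage, of the genes of 3 lists in each library (grey points WT, orange points CKO, numbers the replicates of the ovulated stage, black lines each group's mean with SD bars). Each ovulated library lay below each GV library in the 3 lists, and ovulated CKO replicates 1 and 2 lay above the 3 ovulated WT libraries for complex I, at 5.19 and 4.42 against at most 3.64.

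Each ovulated library was also scored for how close it stood to the GV profile. On a scale where 0% is the mean of the other ovulated libraries and 100% the GV mean, computed without the genes of these lists or the mitochondrial ribosomal proteins, CKO replicates 1, 2 and 3 stood at 27.3%, 21.1% and −14.7% and WT replicates 1, 2 and 3 at −19.1%, −2.76% and 7.19%. The CKO mean was 16.1% closer to GV, a difference that did not pass a two-sided exact permutation test (p = 0.3, where 0.1 is the smallest p that 3 against 3 libraries allow).

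The number of genes called in ovulated oocytes depended on CKO replicate 3 and on the fit. Without that library edgeR called 201 of 12576 genes, 196 higher and 5 lower, and without WT replicate 3 it called 3. The 201 included Mt1 (6.02, adjusted p = 0.00831), Psmb7 (4.60), Chchd2 (4.29), Ndufa5 (3.24) and Cox7c (4.20), and 8 of 36 complex I genes, 7 of 40 genes of complexes II to V and 6 of 78 cytosolic ribosomal protein genes rose. So did 2 of 31 genes of mitochondrial import and dynamics, 4 of 40 maternal-effect genes and 3 of 31 oocyte transcription factor, zona and secreted factor genes. The counts were 2 of 22 for heme and iron-sulfur cluster genes, 3 of 36 for proteasome genes and 5 of 77 for mitochondrial ribosomal protein genes. With the 6 libraries DESeq2 called 101 genes (96 higher, 5 lower) and limma-voom 1, and the edgeR fit of the 14 libraries called 64 (61 higher, 3 lower). On simulated counts of the ovulated design, with 200 genes changed, DESeq2 called 32 unchanged genes, edgeR 5 and limma-voom 7. Again these are not the false calls to expect in the real libraries. Genes with a count numbered 14223 ± 660 (SD, n = 3) in WT and 14346 ± 280 (SD, n = 3) in CKO, a difference of 122 (exact permutation test, two-sided, p = 0.7) whose sign turned without WT replicate 1 (−146) or CKO replicate 2 (−7.83).

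The third comparison asked where the effect of losing Clpx differed between the stages. Tti2, which encodes a cochaperone for kinases of the PIKK family, was the 1 gene of 13158 that passed in edgeR. Its counts in ovulated WT libraries summed to 1 and in ovulated CKO libraries to 105, a ratio of 96.8 per library size with a 95% counting interval of 17 to 3860. In GV oocytes Tti2 stood at 3.65 ± 0.874 CPM (SD, n = 4) in WT and 2.97 ± 1.59 CPM (SD, n = 4) in CKO. As a set, complex I genes had a higher CKO effect in ovulated than in GV oocytes, in 33 of 36 genes with a median difference of 1.08 on the log2 scale, a call that was lost with an estimated correlation (adjusted p = 0.957).

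Tti2 (gene ID 234138, chromosome 8, 31150316 to 31164703) had a fitted difference of 6.41 (SE 0.904, edgeR adjusted p = 0.0254), a size that depends on the prior count. It lay below the expression level that the rule for named genes asks for and was chosen after its values were seen. The next 10 genes did not pass (edgeR adjusted p from 0.221 to 0.28). Higher CKO effects in ovulated oocytes were fitted for Znrd1 (4.18), Psmb7 (3.99), the neuropeptide gene Nmu (3.79), Tsacc (3.62), Slirp (3.51), Yipf1 (3.33), Tmem29 (3.06) and the transporter gene Slco4a1 (1.68). Lower effects were fitted for Gm20594 (−2.35, adjusted p = 0.221) and Teddm1b (−1.81). Gm20594 stood at 203 ± 69.9 CPM (SD, n = 3) in ovulated WT and 337 ± 172 CPM (SD, n = 3) in ovulated CKO oocytes.

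Complex I was the 1 list of 30 called for the stage difference (adjusted p = 6.95e-07), with Ndufa5 (2.55) as an example. With an estimated correlation it had adjusted p = 0.957, and leaving out a library gave 1 to 5 lists. Complexes II to V had a median of 0.66 (adjusted p = 0.0987) and the mitochondrial unfolded protein response list 0.20 (adjusted p = 0.944). The 1 gene was lost with limma-voom, with both FPKM fits, with a replicate block and in 11 of the 14 fits that leave out a library. With a minimum of 10 CPM it was left out before the test. DESeq2 called 65 genes (61 higher, 4 lower), 1205 genes had an unadjusted p under 0.05, and without ovulated CKO replicate 3 edgeR called 498 (489 higher, 9 lower).

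The fourth comparison described how WT oocytes differed between the stages, as background for the effects of genotype. Ovulated WT oocytes had lower shares of counts from genes of the ribosome and the respiratory chain than GV WT oocytes. These sets were called by camera with the preset correlation and not with an estimated one (adjusted p = 0.69). Zp3, which encodes a zona pellucida glycoprotein, fell 41.6-fold, from 4583 ± 667 CPM (SD, n = 4) to 110 ± 7.08 CPM (SD, n = 3). The uridine phosphorylase gene Upp1 fell 606-fold, from 582 ± 184 CPM (SD, n = 4) to 0.945 ± 0.624 CPM (SD, n = 3). Transcripts of maternal mRNA storage and decay factors ranked higher, a call lost in the same way (adjusted p = 0.69), for example the terminal uridylyltransferase gene Tut7, which rose 5.43-fold from 10.7 ± 1.01 CPM (SD, n = 4) to 58.1 ± 14.3 CPM (SD, n = 3).

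Of 13158 genes, 8376 passed in edgeR, 3904 higher and 4472 lower in ovulated oocytes. The stages were deposited as separate tables, so stage and table or batch cannot be told apart in this comparison. Under scaling to total counts the median of all genes shifted by 0.339, and 4471 genes were higher and 3515 lower. All values are shares of each library's counts. They cannot separate a change in the amount of a transcript from a change in how well it was copied into cDNA.

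Among genes that met the rule for named genes, the largest falls after Upp1 were those of Cpsf4l (−8.04), Fam187b (−7.29), the complex I assembly factor gene Ndufaf3 (−7.13) and Ppie (−7.00). The largest rises among them were those of Rpia (4.27), the ubiquilin gene Ubqln2 (4.03), Pdap1 (3.91), Ttyh3 (3.84) and Rtf1 (3.64), a transcription elongation factor gene. These genes had edgeR adjusted p between 1.75e-07 and 8.19e-05.

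Of 30 lists, 6 ranked lower and 1 higher in ovulated WT oocytes by camera, and each had adjusted p = 0.69 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 70 fell and 1 rose (median log2 fold change −3.07, adjusted p = 3.72e-12), for example Rpl7a (−5.00). Of 36 complex I genes, 30 fell and 1 rose (median −2.89, adjusted p = 3.64e-07), for example Ndufa9 (−6.25). Of 40 genes of complexes II to V, 34 fell and 1 rose (median −2.48, adjusted p = 2.52e-07), for example the ATP synthase genes Atp5g1 (−4.55) and Atp5o (−4.18). Of 78 mitochondrial ribosomal protein genes, 56 fell and 7 rose (median −2.02, adjusted p = 3.13e-07), for example Mrpl17 (−4.43) and Mrpl37 (−3.07). Of 36 proteasome genes, 23 fell and 5 rose (median −1.93, adjusted p = 0.0011), for example Psmc2 (−4.80) and Psmc1 (−2.79). Of 32 genes of mitochondrial import and dynamics, 23 fell and 5 rose (median −1.82, adjusted p = 0.00327), for example Timm50 (−5.25) and Tomm22 (−3.17). Of 51 genes of maternal mRNA storage, polyadenylation and decay, 25 rose and 9 fell (median 0.98, adjusted p = 0.00806), for example Upf1 (2.72) and Tut7 (2.44). These 7 directions were the same under the other scalings.

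Lists that were not called as a set still held many genes that passed, in a comparison where 63.7% of all tested genes did. Counts near that share are therefore not a result about a list. The granulosa and cumulus markers passed less often than that. Of 31 oocyte transcription factor, zona and secreted factor genes, 14 fell and 7 rose, with Zp1 at −4.99. Of 27 genes of mitochondrial proteases, chaperones and the mitochondrial unfolded protein response, 14 fell and 5 rose, with the chaperone gene Trap1 at −3.44. Of 63 genes of the meiotic cell cycle, spindle and cohesin, 28 rose and 21 fell, with Sgo2a, a protector of centromeric cohesin, at 1.86 and the spindle gene Tacc3 at −3.36. Of 40 maternal-effect genes, 12 rose and 16 fell, with Dnmt3l at −3.66. Of 21 cytosolic heat shock chaperone genes, 12 fell and 5 rose, with Hspa8 at −4.31. Of 18 granulosa and cumulus markers, 4 rose and 1 fell, with Kitl at 1.54 and Cyp11a1 at −1.97, and of 7 markers of theca, stromal, endothelial and blood cells, 4 rose and 1 fell, with Kdr at 2.51 and C1qb at −4.06.

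**Figure D3:**
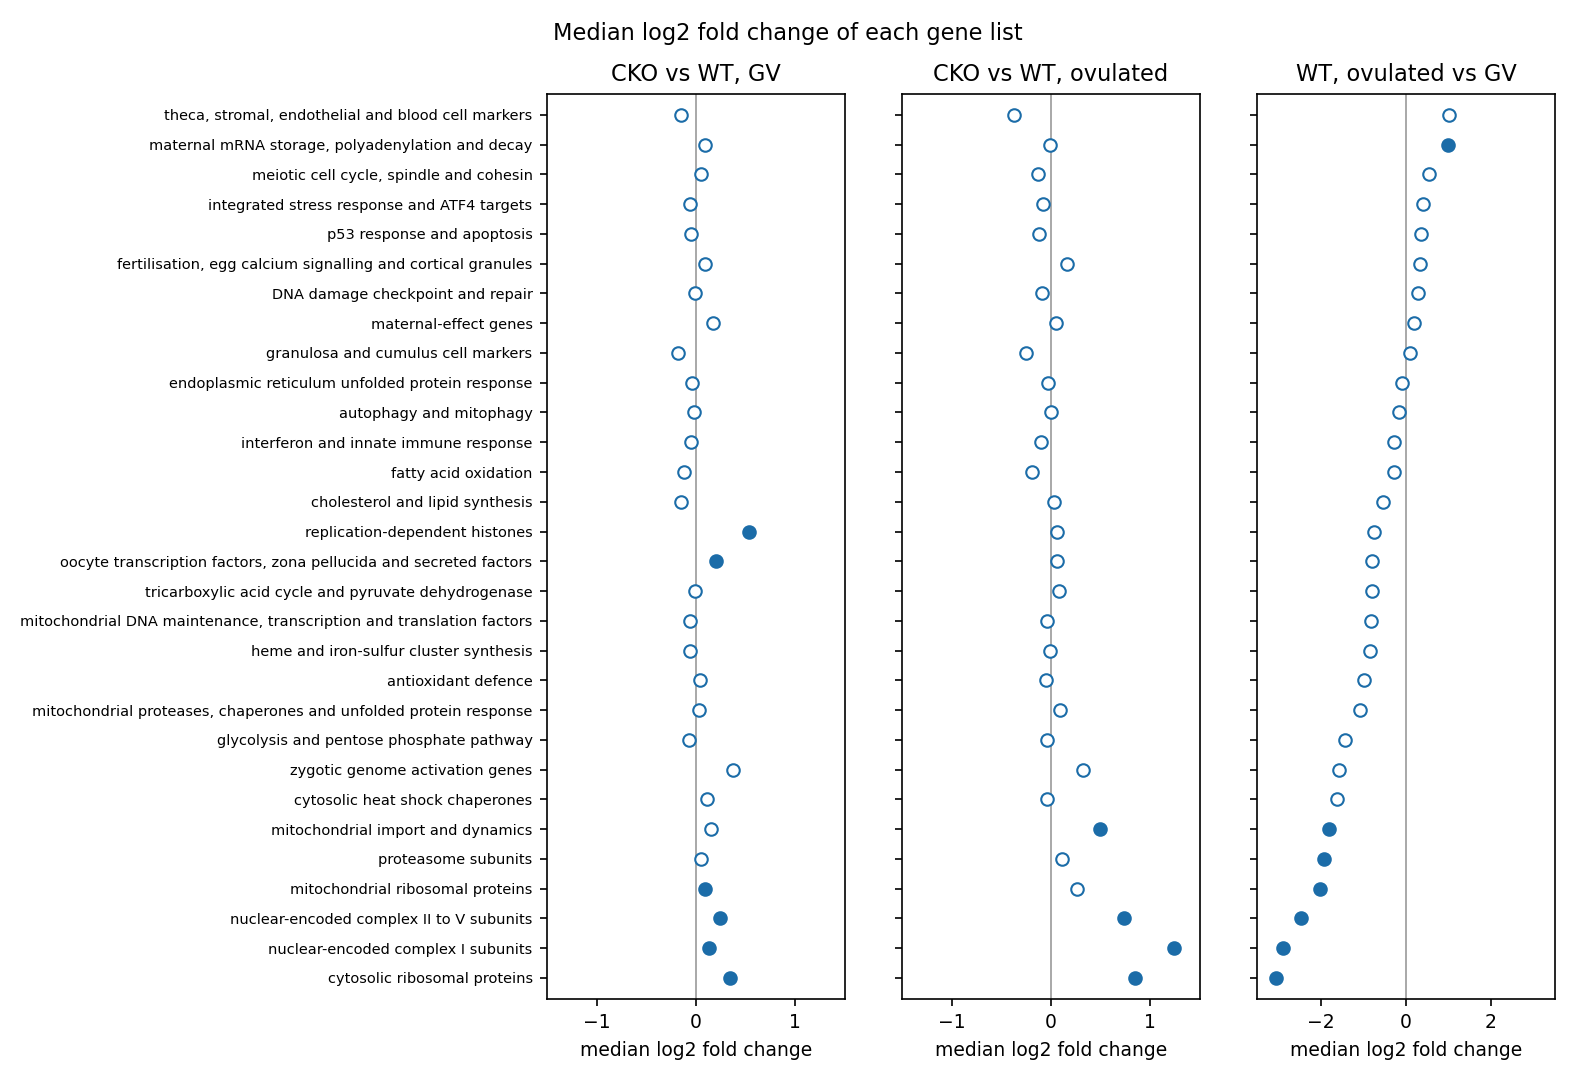
Median log2 fold change of each gene list for CKO against WT in GV oocytes, CKO against WT in ovulated oocytes and ovulated against GV in WT oocytes (the last with a wider axis). Filled points are lists called by camera with the preset correlation, and the lowest WT stage median was that of cytosolic ribosomal proteins (−3.07). The ovulated WT libraries enter both of the last comparisons on opposite sides, so opposite signs there can come from these libraries alone.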

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

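The metallothionein, other cell type, transgene and closeness tests below were chosen only after the result was seen.

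Mt1 was higher in 7 of 7 CKO libraries than in every WT library of their stage, at 99.5 ± 14.2 CPM (SD, n = 4) in GV and 63 ± 34.4 CPM (SD, n = 3) in ovulated CKO oocytes. Induction of metallothionein genes by metal or stress would raise Mt2 with Mt1, and the higher of the stage means of Mt2 in CKO libraries was 0.354 CPM, against 0.37 and 0.201 CPM in WT. RNA of other ovarian cells would raise granulosa and cumulus markers, whose higher stage median was −0.18 on the log2 scale, with the granulosa gene Inha at 1.04 CPM in GV CKO and 1.02 CPM in GV WT oocytes. A candidate explanation that remains is Mt1 sequence carried by the Zp3-Cre transgene, whose parts other than the promoter and Cre are not given in the labels, and it cannot be told apart from a change of Mt1 itself because transgene and genotype coincide in all 7 CKO libraries and the tables hold no read positions. A change of Mt1 itself caused by loss of CLPX stays open and untested.

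Complex I transcripts ranked higher in ovulated CKO oocytes, with a median of 1.19 on the scale of log2 CPM used for these tests. Removing each library's trend on GC content and transcript length moved other genes by 0.0981 at the median and left 0.819 (camera adjusted p = 4.78e-08), which argues against that trend as the whole cause. Across the 6 ovulated libraries of both genotypes, the complex I mean followed closeness to the GV profile (Pearson r = 0.924, exact permutation p = 0.00833, Spearman rho = 0.943, exact permutation p = 0.0167, and r = 0.809 without the 2 libraries farthest from the median). With that score as a covariate the median was 0.425 and the list was still called (adjusted p = 0.0229), though these calls used the preset correlation and the list was not called with an estimated correlation before either adjustment (adjusted p = 0.881). The correlation ignored genotype, and the order held within CKO but not within WT. There replicate 3 stood closest to GV (7.19%) with a complex I mean of 3.19, below the 3.64 of replicate 2 (−2.76%). Complex I also fell from GV to ovulated WT oocytes (median −2.89), so a link with closeness to GV was in part built in. CKO replicates 1 and 2 may have moved less far from the GV profile. Whether loss of CLPX slows that move or the libraries differed for another reason stays open.

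Gm20594 was higher in the 4 GV CKO than in the 4 GV WT libraries, with a log2 fold change of 3.08. Its transcript matched the mitochondrial large ribosomal RNA with 88.506% identity over an alignment of 435 positions, short of the 90% set for an assignment, so reads of that RNA may or may not be counted there and the sources cannot be told apart. Whether mitochondrial RNA as a whole was higher could not be tested. The search covered protein-coding transcripts alone, and among these the number of other tested genes that matched mitochondrial transcripts was 0. An effect of CLPX loss on mitochondrial ribosomal RNA or on Gm20594 itself stays open as a biological explanation.

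The effect of CKO on Tti2 was called different between stages, by a fitted 6.41 on the log2 scale (interaction test, edgeR adjusted p = 0.0254). The call rested on 1 count in ovulated WT and 105 in ovulated CKO libraries. It was lost with limma-voom, with either FPKM fit, with a replicate block and in 11 of the 14 fits that leave out a library. Of 100 drawn splits, 24 called at least 1 gene. The complex I list was called too, with a median difference of 1.08 (camera adjusted p = 6.95e-07, and adjusted p = 0.957 with an estimated correlation).

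In 136 groups of 4 libraries, 8 had a library far from the other 3, where chance gives about 1 in 20 groups; the ratio of the gap to the range is given for each. Clpx in GV WT oocytes was 51.5 CPM in replicate 1 and 33.6 to 35.2 CPM in the others (0.911). Mt1 in GV CKO oocytes was 78.5 CPM in replicate 4 and 104 to 108 CPM in the others (0.856). Gtf2ird1 in GV WT oocytes was 87.7 CPM in replicate 3 and 101 to 103 CPM in the others (0.845). The mean of complexes II to V in GV CKO oocytes was 6.42 log2 CPM in replicate 3 and 6.56 to 6.58 in the others (0.843). In the fit of 14 libraries, GV WT libraries stood apart for Urod (0.858; 98 against 85.4 to 87.2 CPM), Alad (0.936; 19.8 against 16.9 to 17.1 CPM), Cdkn1a (0.841; 0.822 against 0.452 to 0.511 CPM) and Zp3 (0.863; 5576 against 4159 to 4353 CPM).

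Other splits of the same libraries were fitted to see how often they gave as many calls. For GV genotypes, 3 of the 35 splits gave at least the 3 genes of the real one and the highest of the others gave 20, and 19 of 35 gave at least its 6 lists (highest other 12), so chance is not excluded for either count. For ovulated genotypes the 10 splits are too few for a share under 0.05; 2 of them gave at least 1 gene and 5 at least 4 lists, with 888 genes and 10 lists as the highest of the others. The split with 888 genes set WT replicates 1 and 3 and CKO replicate 3 against the rest, which points to a structure of the samples other than genotype. For the WT stages, 1 of 35 splits, the real one, gave 8376 genes and the highest other gave 2816, so chance is excluded for the genes, while 18 of 35 gave at least 7 lists (highest other 12), so it is not excluded for the lists. For the stage difference, 24 of 100 drawn splits gave at least 1 gene (highest other 591) and 91 gave at least 1 list (highest other 14), so chance is not excluded.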

How the results depend on the processing

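The average of both stages was the 1 alternative chosen only after the result was seen. Clpx fell under every setting tried, with log2 fold changes from −5.53 to −3.61 in GV and from −5.63 to −2.90 in ovulated oocytes, and Mt1 and Gm20594 rose in GV oocytes in all 19 settings each. For GV genes, DESeq2 called 39 and limma-voom 6, each including the same 3, and leaving out a library gave 3 to 6 (6 without CKO replicate 1 or CKO replicate 4). For ovulated genes, DESeq2 called 101, the fit of the 14 libraries 64 (61 higher, 3 lower), and leaving out a library gave 1 to 201 (201 without CKO replicate 3, 3 without WT replicate 3). For the stage difference, DESeq2 called 65, while limma-voom, a minimum of 10 CPM, FPKM + 1 and FPKM + 0.1 called 0, and leaving out a library gave 0 to 498 (498 without ovulated CKO replicate 3). WT stage genes ranged from 5761 with a minimum of 10 CPM, where fewer genes were tested, to 8691 with DESeq2. With an estimated correlation and with fry, 0 lists were called for GV genotypes, ovulated genotypes and the stage difference; for the WT stages the counts were 0 and 21. Leaving out a library gave 3 (without WT replicate 3) to 10 (without WT replicate 4) GV lists, 1 (without WT replicate 1 or CKO replicate 1) to 6 ovulated lists and 1 to 5 lists for the stage difference (5 without ovulated CKO replicate 3). For genes with a count in GV oocytes, leaving out a library gave differences from −557 (without CKO replicate 3, exact p = 0.0286) to −305. Thinning to the smallest total gave −370 (exact p = 0.171) and a minimum of 10 counts −279 (exact p = 0.286). In ovulated oocytes leaving out a library gave −146 (without WT replicate 1) to 491 (without WT replicate 3), and −7.83 without CKO replicate 2. Clpp in GV oocytes, which never passed, turned sign with total counts (−0.13), limma-voom (−0.06011), FPKM + 1 (−0.10) and FPKM + 0.1 (−0.11), and leaving out a library gave −0.06889 to 0.2429. The cause of these differences was not tested. Replicate numbers were not taken to pair the samples, since CKO and WT libraries of the same number did not all correlate above 0.1 (−0.249, 0.196, 0.334 and 0.332 for GV numbers 1 to 4, −0.235, 0.261 and −0.0195 for ovulated numbers 1 to 3). WT libraries of GV numbers 3 and 4 and ovulated number 2 correlated best with their own number and the others did not, a hint from the data that leaves shared handling of some numbers open. The TMM scaling factors of the GV libraries ranked by number in the same order in both genotypes. For numbers 1 to 4 they were 1.206, 0.9832, 1.277 and 0.8385 in WT and 1.07, 0.8376, 1.198 and 0.7334 in CKO. A replicate block gave 3 GV genes, 1 ovulated gene and 0 for the stage difference, and 5, 4 and 1 lists. The alternatives for the mitochondrial DNA share were not run, since its genes are not listed. At this number of libraries, changes of 2-fold in ovulated oocytes were recovered in 5% of simulated genes.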

Other observations

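The tests of the average effect and of genes near Clpx were chosen only after the result was seen.

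Across the 11478 genes tested at both stages, the CKO effects in GV and ovulated oocytes had a Pearson r of 0.178 and a Spearman rho of 0.171, across genes, which are not independent replicates. At an unadjusted edgeR p under 0.01 in both stages there were 8 genes, where 2.91 are expected if the stages were independent. The 8 had the same sign at both stages. They include Clpx, deleted by design at both stages, and Mt1, which the transgene may carry, so part of this overlap was set by the design. Besides Clpx and Mt1 these were Ptgds, which encodes a prostaglandin D synthase (log2 fold change 2.52 in GV and 2.90 in ovulated oocytes), Gm29797 (1.18 and 3.39), Gli3 (2.03 and 1.17), the carboxylesterase gene Ces1d (−1.34 and −1.99), the homeobox gene Hoxa7 (−0.89 and −1.13) and Trpm6, a magnesium channel gene (−0.68 and −1.36). Apart from Clpx at both stages and Mt1 in GV oocytes, none of these passed in edgeR within a stage.

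In the average of both stages, edgeR called 5 of 13158 genes, 3 higher and 2 lower: Clpx (−5.34, adjusted p = 1.83e-09), Mt1 (5.84, adjusted p = 9.07e-06), Gm20594 (1.91, adjusted p = 0.00182), Tti2 (2.90, adjusted p = 0.024) and Myo1e (−1.15, adjusted p = 0.024). The Tti2 average came from the ovulated stage, with 1 count in WT and 105 in CKO libraries, while in GV oocytes Tti2 stood at 3.65 CPM in WT and 2.97 CPM in CKO. Myo1e stood at 26.1 ± 2.01 CPM (SD, n = 4) in GV WT, 10.1 ± 3.13 CPM (SD, n = 4) in GV CKO, 17.7 ± 0.214 CPM (SD, n = 3) in ovulated WT and 9.1 ± 1.34 CPM (SD, n = 3) in ovulated CKO oocytes. Of 100 drawn splits, 17 gave at least 5 genes (highest other 973) and 39 at least 6 lists (highest other 13), so chance is not excluded for these counts. DESeq2 called 313 genes and limma-voom 253 for the same average, total counts gave 3, and without ovulated CKO replicate 3 edgeR called 733.

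Myo1e lies 4.91 Mb from Clpx on chromosome 9. Of the genes within 10 Mb of Clpx, 9 of 143 had an unadjusted p under 0.05 in GV oocytes (6.29%, against 5.73% elsewhere) and 15 of 138 in ovulated oocytes (10.9%, against 7.73%).

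Some genes of mitochondrial and integrated stress responses, chosen after their values were seen, had log2 fold changes that did not pass. In GV and ovulated oocytes in turn, the chaperonin genes Hspd1 and Hspe1 had 0.18 and −0.16, and 0.65 and 0.02. The protease gene Lonp1 had 0.01 and 0.71, and the transcription factor genes Atf4 and Ddit3 had 0.22 and −0.00058, and 0.04 and 1.00.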
